A study of Mus musculus with 19 samples.

How the data were processed

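Liver RNA from 19 male C57BL/6JRj mice with diet-induced obesity and fatty liver disease was sequenced, 1 library per animal. Per the labels, 10 animals received vehicle and 9 received an siRNA. The mice were fed the GAN diet, a fat-, fructose- and cholesterol-rich diet used to produce steatohepatitis, and each label gives an age of 5 weeks; whether that is the age at the start of the diet or at sampling is not stated. Per the labels' protocols, liver pieces were kept in RNAlater, libraries were made with NEBNext Ultra II Directional reagents and sequencing was done on a NextSeq 500. The siRNA's target is not named in the labels. It was taken as Mtarc1 because the series title names mARC1, and its level was checked in every library. The control was vehicle and not a control siRNA, so effects of the knockdown cannot be separated from effects of siRNA delivery or of unintended targets.

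The authors deposited 1 table of read counts per gene, not normalised, for 55536 Ensembl genes and all 19 libraries. The submitters' processing notes name STAR as the aligner and mm10 as the genome build. The counting program, its strand setting and the annotation release are not given in the sources used here. Counts were whole numbers and every one of the 19 columns matched 1 sample by its label. Of the gene identifiers, 55450 were found in the GENCODE M21 annotation (GRCm38, which is mm10) and 86 were not; symbols came from the table itself, in which 118 entries had a symbol shared with another entry. Coordinates are from GENCODE M21. Reads that fit more than 1 gene could be lost or split by the authors' counting, so values of members of near-identical families (Cyp2a, Cyp2c, Cyp2d, Cyp3a, Cyp4a, Gsta, Mup, Hamp, Orm, C4, Slc22a and carboxylesterase genes) are uncertain, as are those of antisense or overlapping genes, because the strand setting is unknown.

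Total counts per library ranged from 12165263 to 22237798 reads. No library pair was a repeat of the other: over genes with at least 20 counts in the pair, the chi-square per degree of freedom was 8.58 to 91.9 over 171 pairs. Replicate numbers follow the order of the samples and pair nothing. The labels give no batch.

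Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (minimum count 10, minimum total 15), library sizes were scaled by TMM, and a robust quasi-likelihood fit with 1 term for group was tested for siRNA against vehicle, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are log2 values of siRNA over vehicle. Their approximate standard error (SE) is the absolute log2 fold change divided by the square root of the test's F value. Levels are CPM, read counts scaled to a common library size, computed here from the counts and TMM factors, given as mean ± SD over 10 vehicle and 9 siRNA libraries. Mtarc1 and Mtarc2 were also compared by a two-sided exact permutation test of log2 CPM over all 92378 splits. Log CPM used a prior count of 2.

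Gene lists for liver metabolism, injury, stress and cell types were fixed before the data were examined, as were the designs, the alternatives and the rule for naming genes, except where stated. Of the lists, 40 had at least 5 members that passed the filter. Each was tested with camera in limma 3.58.1 (preset inter-gene correlation of 0.01), which asks whether members stand higher or lower than all other genes, with adjustment over the 40 lists. Camera with an estimated correlation and fry, a rotation test of a one-way shift of the list itself, were run beside it. The SE of a list's mean is over its members, so it leaves out variation between animals. The rule named Mtarc1 and Mtarc2, the 12 higher and the 12 lower genes with the smallest p at a mean of at least 1 CPM in the higher group (predicted genes left out), up to 4 members of each list past the threshold, and, for a list with none, up to 4 past it over the list alone or otherwise up to 2 of the most abundant members.

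The test was checked on simulated counts for 14235 genes drawn from these libraries' means and sizes. It recovered 42% of genes changed 1.3-fold, 70% of those changed 1.5-fold, 92% of those changed 2-fold and 94% of those changed 4-fold, 50 genes each, with 2 false calls among 14035 unchanged genes. A planted list of 25 genes changed 1.3-fold was called and none of 20 random lists was, in a simulation in which genes varied independently; camera's preset correlation was not tested there on genes that vary together. The search for sequence motifs recovered 20 of 20 planted heptamers.

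The alternatives were RLE and upper-quartile scaling, the DESeq2 1.42.0 Wald test, limma voom with quality weights, no filter beyond a total above 0, a filter at a mean of 1 CPM, and covariates (the file number in the labels, 1 surrogate variable from sva 3.50.0, and the hepatocyte marker sum). Further ones were an adjusted p under 0.1, a minimum fold of 1.2, and leaving out each library. Another left out siRNA 4, farthest out on the first principal component, and vehicle 10 and siRNA 8, farthest out on the second. It was chosen after seeing the data. These are called the 3 libraries farthest out below. siRNA 2 (-30.9 on the first component) was kept, although it lay about as far out as siRNA 8 (-29.9 on the second). The gene test and the list test were also run on 100 splits of the 19 libraries into 10 and 9, the real one included. Heptamers in annotated 3' UTRs of at least 10 nt were counted for fallen and for risen genes against all tested genes, by a hypergeometric test with Bonferroni adjustment over all possible heptamers, and against 1000 gene sets matched on UTR length in 10 strata. Sorting, motif counts and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.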

Results

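Bulk liver RNA was profiled in obese mice with diet-induced fatty liver disease, 10 given vehicle and 9 given an siRNA, each library from a separate animal. The series title places the study around hepatocyte mARC1, a molybdenum-containing reductase of the outer mitochondrial membrane encoded by Mtarc1. The comparison asks which liver transcripts differ between siRNA-treated and vehicle-treated animals. Total counts were 16817230 ± 2496362 reads in vehicle libraries (SD, n = 10, range 12165263 to 21335001) and 17129146 ± 2412264 reads in siRNA libraries (SD, n = 9, range 13819419 to 22237798). The 10 most counted genes of each library held 16.8 ± 0.921% of vehicle counts and 15.7 ± 0.707% of siRNA counts (SD), and mitochondrially encoded genes 4.30 ± 0.436% and 4.62 ± 0.674%. Of 55536 genes in the table, 14235 passed the filter on low counts. The first 3 principal components held 24.4%, 14.9% and 12.9% of the variance, and on the third all vehicle libraries lay above 0 and all siRNA libraries below it.

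Mtarc1 (listed as Marc1, ENSMUSG00000026621, minus strand of chromosome 1, 184786767 to 184811313 in GRCm38) was strongly reduced in every siRNA liver. Its level fell from 333.7 ± 47.0 CPM in vehicle (SD, n = 10) to 20.8 ± 3.6 CPM in siRNA libraries (SD, n = 9), which left 6.24% of the vehicle level (95% interval 5.31 to 7.33%), a reduction of 93.8%. The log2 fold change was -4.00 ± 0.112 (SE), with an adjusted p of 1.04e-16 in edgeR's quasi-likelihood test. Vehicle libraries lay between 265.9 and 419.9 CPM (3483 to 8005 reads) and siRNA libraries between 15.9 and 26.1 CPM (261 to 470 reads), with an exact permutation p of 2.17e-05, the smallest that the 92378 splits allow. Its neighbour and paralog Mtarc2 (listed as Marc2, ENSMUSG00000073481, minus strand of chromosome 1, 184813068 to 184846451) was at 341 ± 38.5 CPM in vehicle and 340 ± 64.2 CPM in siRNA livers. Its log2 fold change of -0.01 ± 0.0957 (SE) was smaller than the spread between animals (adjusted p = 0.985, exact permutation p = 0.860) and lay between -0.09 and 0.03 with 1 library left out.

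**Figure D1:**
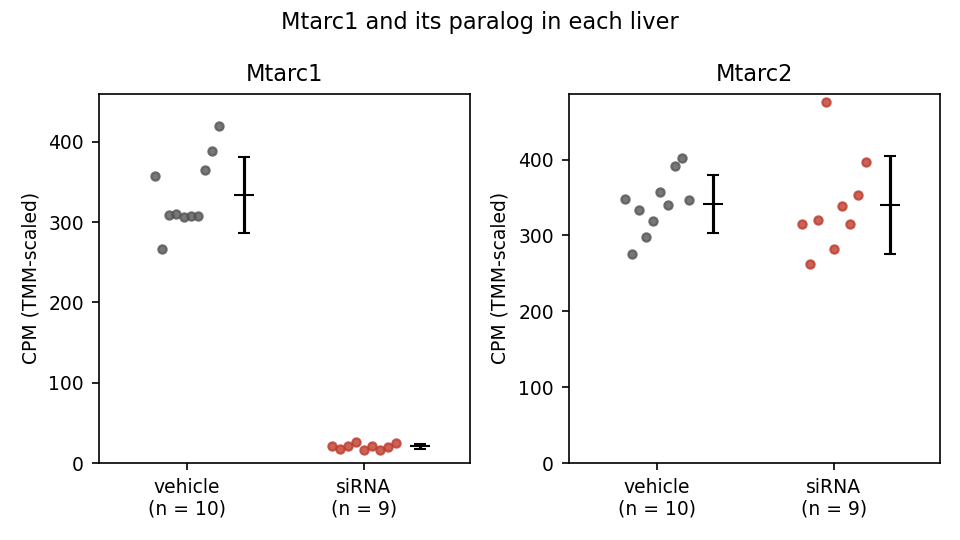
Level of Mtarc1 and Mtarc2 (CPM, linear axis) in each of 10 vehicle and 9 siRNA liver libraries, with group means and SD. All 9 siRNA libraries lie at or below 26.1 CPM for Mtarc1 and all 10 vehicle libraries at or above 265.9 CPM, whereas the groups overlap for Mtarc2.

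Beside Mtarc1, the genes with the smallest p among those that fell included a pair of lysosomal genes, a vesicle tether and a pair of genes for proteins that carry thyroid hormone. Arsb, a lysosomal arylsulfatase that trims glycosaminoglycans (ENSMUSG00000042082, chromosome 13, 93771630 to 93943016), fell from 54.9 ± 5.28 to 20.96 ± 1.66 CPM (log2 fold change -1.39 ± 0.0648 SE, adjusted p = 2.75e-12). Cln5, another lysosomal protein (ENSMUSG00000022125, chromosome 14, 103070216 to 103077628), fell from 45.7 ± 3.41 to 21.1 ± 1.81 CPM (log2 fold change -1.11, adjusted p = 3.41e-11). Lower genes also included Uso1, a vesicle tether of the early secretory pathway (-1.04), and Serpina7, the thyroxine-binding globulin (-1.17). Slc16a2, a thyroid hormone transporter (-0.82), Mapk3, an extracellular signal-regulated kinase (-0.85), and Cdh2, N-cadherin (-0.78), fell as well. So did Ttc7b (-0.77), Ociad2 (-0.70), Odr4 (-0.59) and Pcnp (-0.53). For each of these 11 genes all 9 siRNA libraries lay below all 10 vehicle libraries.

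The genes with the smallest p among those that rose included glypican 3, a cell-surface proteoglycan abundant in fetal liver, the keratin gene Krt23 and the plastin gene Pls1. Gpc3 (ENSMUSG00000055653, chromosome X, 52272426 to 52613950) rose from 0.976 ± 0.356 to 3.67 ± 0.680 CPM (log2 fold change 1.91 ± 0.181 SE, adjusted p = 8.13e-07). Krt23 (1.62), Pls1, whose product bundles actin (1.54), and Lad1, a ladinin of epithelial attachment (0.97), rose too. The glutathione transferase gene Gsta2 (1.10), the ectodysplasin gene Eda (0.98), Sh2d4a (0.80), the LIM-domain gene Ajuba (0.79) and Cyp3a59 (0.78) followed. Fam234b (0.61), the metalloreductase gene Steap3 (0.49) and the adenosine receptor gene Adora1 (0.43) completed the 12, with adjusted p between 5.84e-07 and 0.000444.

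**Figure D2:**
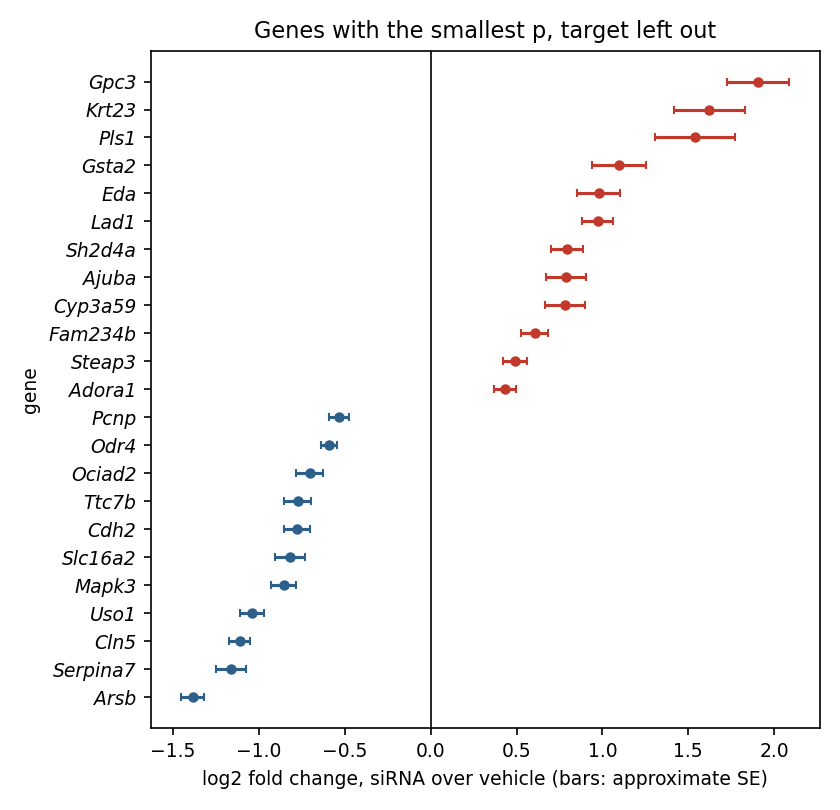
Log2 fold change of siRNA over vehicle (points, with approximate SE as bars) for the 12 higher and 11 lower genes with the smallest p, Mtarc1 left out. Values run from -1.39 for Arsb to 1.91 for Gpc3.

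In all, 480 of 14235 genes changed (3.37%), 232 higher and 248 lower, and the changes were mostly small. The median absolute log2 fold change of the changed genes was 0.468. At 1.5-fold or more, 74 genes were higher and 112 lower, and at 2-fold or more 25 were higher and 28 lower. All siRNA libraries lay below all vehicle libraries for 36 genes and above them for 24, where chance gives 0.00108% of genes in each direction, and each of these genes passed the test. The common biological coefficient of variation was 17.3%. Another tool or filter moved the count by more than 1.5 times: DESeq2 called 766 genes, a surrogate variable or the hepatocyte marker sum as a covariate gave 1491 and 1002, and no filter on low counts left 289.

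Lists of fat synthesis and fat storage genes stood lower in siRNA livers, with 4 of 22 and 3 of 28 members past the test. The adjusted camera p was 7.36e-05 for lipogenesis and 6.60e-05 for triglyceride genes (adjusted p = 0.455 with an estimated correlation for each). Of 22 de novo lipogenesis genes, 4 fell, none rose and 18 did not pass (7 fell when adjusted over the list alone); the mean log2 fold change was -0.25 ± 0.0630 (SE over members). Scd1, the stearoyl-CoA desaturase, fell from 33760 ± 7110 to 23660 ± 4410 CPM (log2 fold change -0.51, adjusted p = 0.0240). The others were Aacs, an acetoacetyl-CoA synthetase (-0.80), the ATP citrate lyase gene Acly (-0.69) and the elongase gene Elovl6 (-0.65). Of 28 genes of triglyceride synthesis and lipid droplets, 3 fell, none rose and 25 did not pass (5 fell when adjusted over the list alone). That list's mean log2 fold change was -0.24 ± 0.0896 (SE over members) and its median -0.10. Cidea, which promotes lipid droplet growth, fell from 22.1 ± 11.4 to 4.07 ± 1.82 CPM (log2 fold change -2.46 ± 0.302 SE, adjusted p = 3.23e-05). Cidea is also 1 of the 6 adipocyte markers, a list that stood lower as well (mean -0.66 ± 0.542, median -0.18, adjusted camera p = 0.0298, adjusted p = 0.455 with an estimated correlation), with the adipsin gene Cfd at -2.08. The glycerol channel gene Aqp7 of that list rose. Both lists thus hold Cidea, and neither was tested without it. Fitm2, needed for droplet formation (-0.50), and the droplet coat gene Plin2 (-0.46) fell less. The calls of Acly and Elovl6 ended without any 1 of 13 and 15 of the 19 libraries (adjusted p up to 0.143 and 0.146 over the alternatives). Both also ended without a filter on low counts, that of Acly without the 3 libraries farthest out and that of Elovl6 with the file number as a covariate.

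Targets of PPAR-alpha, the receptor that drives fatty acid breakdown, stood lower as a list, whereas the list of mitochondrial fatty acid oxidation and ketogenesis genes did not pass. Of 28 PPAR-alpha targets, 5 fell, none rose and 23 did not pass (11 fell and 2 rose when adjusted over the list alone); the mean log2 fold change was -0.23 ± 0.0616 (SE) and the adjusted camera p 7.63e-06 (adjusted p = 0.455 with an estimated correlation). Acox1, the first enzyme of peroxisomal beta-oxidation, fell from 3427 ± 542 to 2571 ± 284 CPM (log2 fold change -0.41, adjusted p = 0.0142). Cyp4a14, a fatty acid hydroxylase (-1.04), Crat, a carnitine acetyltransferase (-0.41), and the aldehyde dehydrogenase gene Aldh3a2 (-0.35) fell too. Of 23 genes of mitochondrial fatty acid oxidation and ketogenesis, 1 rose, none fell and 22 did not pass, the same when adjusted over the list alone, with a mean of -0.01 ± 0.0278 (adjusted camera p = 0.525). The riser was Acat1, a thiolase (0.31, adjusted p = 0.00400). Without the 3 libraries farthest out the calls of Cyp4a14 and Crat ended, and without a filter on low counts those of Cyp4a14 and Aldh3a2 (adjusted p up to 0.0817, 0.0789 and 0.0510 over the alternatives of Cyp4a14, Crat and Aldh3a2).

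Single genes of lipid transport, cholesterol and phospholipid pathways changed, but these lists as wholes did not pass. Of 33 lipoprotein genes, 1 rose, 2 fell and 30 did not pass (2 and 2 when adjusted over the list alone; adjusted camera p = 0.173). Vldlr, the very-low-density lipoprotein receptor, fell from 10.5 ± 2.53 to 4.70 ± 1.08 CPM (log2 fold change -1.15 ± 0.148 SE, adjusted p = 5.28e-05). The carboxylesterase gene Ces1f fell (-0.39) and Scarb1, a receptor for high-density lipoprotein, rose (0.26). Of 25 cholesterol synthesis and uptake genes, 1 rose, the squalene epoxidase gene Sqle (0.80, adjusted p = 0.0452), none fell and 24 did not pass, the same when adjusted over the list alone. The cholesterol list's mean (0.02) and test were positive and its median (-0.04) negative (adjusted camera p = 0.670). Of 31 phospholipid genes, 2 rose, none fell and 29 did not pass (3 rose and 2 fell when adjusted over the list alone): Cds2, which makes CDP-diacylglycerol (0.23), and Etnppl, a phosphoethanolamine lyase (0.69). That list's mean was -0.003, its median 0.02 and its test positive (adjusted camera p = 0.928). The calls of Sqle, Scarb1, Etnppl and Ces1f ended without any 1 of 14, 14, 16 and 8 libraries (adjusted p up to 0.0880, 0.123, 0.177 and 0.0620 over the alternatives), and that of Cds2 without a filter on low counts (up to 0.121). Those of Scarb1 and Etnppl also ended without that filter, that of Scarb1 without the 3 libraries farthest out and that of Sqle with upper-quartile scaling.

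Bile acid and drug-metabolising genes moved in both directions. Of 27 bile acid genes, 2 rose, 2 fell and 23 did not pass (3 and 6 when adjusted over the list alone; mean -0.13 ± 0.129 SE, adjusted camera p = 0.261). That mean was -0.04 without vehicle 10. The list's median was -0.07, and its member Slco1a1, at -3.07 and not past the test (adjusted p = 0.0731), weighs on the mean. The efflux pump gene Abcc4 rose from 11.2 ± 2.90 to 20.1 ± 5.33 CPM (log2 fold change 0.85, adjusted p = 0.00246), as did Acox2, a peroxisomal oxidase of bile acid side chains (0.34). Abcb4, the canalicular phospholipid exporter (-0.22), and Cyp7b1, an oxysterol hydroxylase (-0.73), fell. Of 32 xenobiotic metabolism genes, 3 rose, 3 fell and 26 did not pass (4 and 4 when adjusted over the list alone; mean -0.18 ± 0.104, adjusted camera p = 0.179). Cyp2a5 rose from 852 ± 234 to 1442 ± 324 CPM (0.76, adjusted p = 0.00653), with Cyp2c55 (0.76) and the epoxide hydrolase gene Ephx1 (0.32), while Cyp3a11 fell from 3440 ± 541 to 2600 ± 283 CPM (-0.40, adjusted p = 0.0151). The calls of Abcb4 and Cyp7b1 ended without any 1 of 11 and 12 libraries (adjusted p up to 0.178 and 0.179 over the alternatives), and that of Ephx1 without vehicle 1 or siRNA 5, 6 or 9 (up to 0.0574). Those of Abcb4 and Cyp7b1 also ended without a filter on low counts, and that of Abcb4 without the 3 libraries farthest out.

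Interferon-stimulated genes stood lower as a list in siRNA livers, with an adjusted camera p of 7.52e-11 (adjusted p = 0.417 with an estimated correlation). Of 34 type I interferon response genes, 29 had a negative log2 fold change, 7 fell, none rose and 27 did not pass (16 fell when adjusted over the list alone). The mean log2 fold change was -0.29 ± 0.0413 (SE over members). Oasl2, of the oligoadenylate synthetase family, fell from 25.4 ± 3.57 to 17.0 ± 2.96 CPM (log2 fold change -0.58 ± 0.0994 SE, adjusted p = 0.00171). Oas2 (-0.74), the ISG15-removing protease gene Usp18 (-0.52) and the antiviral GTPase gene Mx1 (-0.73) fell too. Markers of macrophages and monocytes averaged -0.16 ± 0.0692 over 22 members, 1 of which fell, when adjusted over the list alone too (adjusted camera p = 0.0817): Ccr2, the monocyte chemokine receptor, fell from 19.7 ± 5.66 to 11.95 ± 2.73 CPM (-0.72, adjusted p = 0.00994). Macrophage markers were lowest in vehicle 10 and siRNA 8, with mean log2 CPM of 3.76 and 4.02 beside 4.42 or more in the other vehicle and 4.51 or more in the other siRNA libraries, while vehicle 10 had the highest interferon mean (4.37). Their mean log2 fold change was -0.24 without vehicle 10, where the list passed camera, and -0.11 without siRNA 8.

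The list of inflammatory mediators stood lower with 2 of 27 members past the test, at an adjusted camera p of 0.000229 (adjusted p = 0.455 with an estimated correlation), and acute-phase genes moved both ways. Of 27 cytokines and chemokines, 2 fell, none rose and 25 did not pass (5 fell and 1 rose when adjusted over the list alone): Il1b, interleukin 1 beta (7.32 ± 2.36 to 4.07 ± 0.887 CPM, log2 fold change -0.84, adjusted p = 0.0140), and the eosinophil-attracting Ccl24 (-1.14). The mean was -0.31 ± 0.0625. Of 30 acute-phase genes, 2 rose, 4 fell and 24 did not pass (2 and 7 when adjusted over the list alone); the mean was -0.08 ± 0.0793 and the adjusted camera p 0.0167 (adjusted p = 0.491 with an estimated correlation). Hamp2, a hepcidin gene, rose from 20.5 ± 15.8 to 65.6 ± 42.4 CPM (1.68, adjusted p = 0.0206) and Lbp, the lipopolysaccharide-binding protein gene, also rose (0.35). The orosomucoid gene Orm2 (-0.88) and the fibrinogen-like gene Fgl1 (-0.73) fell. The acute-phase call ended without vehicle 1 or vehicle 5 (adjusted p up to 0.0712 over the alternatives) and its mean was -0.14 without siRNA 4, the calls of Fgl1 and Lbp without any 1 of 14 and 9 libraries (up to 0.152 and 0.0625). Hamp2, Orm2 and Fgl1 lost theirs without a filter on low counts (up to 0.0750 and 0.0790 for Hamp2 and Orm2), and Il1b with limma voom (0.0521 at most).

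Resident immune cell markers did not pass as lists. The 12 Kupffer cell markers had 0 past the threshold by edgeR (1 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma voom) and a mean of -0.18 ± 0.0640 (adjusted camera p = 0.297); the abundant members Cd5l and Slc40a1 had log2 fold changes of 0.03 and 0.03, which changed sign without vehicle 10 (Cd5l -0.03) and siRNA 7 (Slc40a1 -0.06). Without vehicle 3 the Kupffer mean was -0.03, Cd5l 0.12 and Slc40a1 0.08. T and NK cell markers had 0 of 14 past by edgeR (1 unadjusted, 0 by DESeq2 or voom) and a mean of -0.23 ± 0.0535 (adjusted camera p = 0.131), with values of -0.08 for Cd8a (0.16 without vehicle 7) and -0.45 for Lck. Without vehicle 7 that mean was -0.07, while without siRNA 3 or vehicle 8 (means -0.37 and -0.31) the list passed. B and plasma cell markers had 0 of 11 past by edgeR (2 unadjusted, 0 by DESeq2 or voom) and a mean of -0.18 ± 0.116 (adjusted camera p = 0.593), with -0.83 for Ighm and -0.66 for Igkc; without vehicle 3 the mean was -0.04, Ighm -0.55 and Igkc -0.41. Dendritic cell markers had 0 of 10 past over all genes by edgeR (1 unadjusted, 1 by DESeq2, 0 by voom) and 1 when adjusted over the list alone, Clec10a (-0.72, adjusted p = 0.0566), with a mean of -0.18 ± 0.0911 (adjusted camera p = 0.170). The other 3 lists had 0 past when adjusted over the list alone as well. Only 3 neutrophil genes passed the filter, too few for the list test. Among them S100a8 (-0.75, adjusted p = 0.171) and S100a9 (-0.68, adjusted p = 0.215) did not pass over all genes.

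Extracellular matrix and activated stellate cell genes stood lower as a list, with small changes. Of 42 fibrosis genes, 41 had a negative log2 fold change, with a mean of -0.28 ± 0.0357 (SE over members) and an adjusted camera p of 6.27e-07, against an adjusted p = 0.455 with an estimated correlation. The list's mean ran from -0.34 without vehicle 10 to -0.19 without vehicle 2. A single member fell, none rose and 41 did not pass over all genes, while 3 fell when adjusted over the list alone. The member that fell was Mmp13, a collagenase (4.92 ± 2.63 to 2.33 ± 0.641 CPM, log2 fold change -1.07, adjusted p = 0.0470), whose call ended without any 1 of 14 libraries, with limma voom, without a filter on low counts and without the 3 libraries farthest out (adjusted p up to 0.220 over the alternatives). Quiescent stellate cell markers had 0 of 15 past over all genes or over the list alone by edgeR (0 unadjusted, 0 by DESeq2 or voom) and a mean of -0.02 ± 0.0295 (adjusted camera p = 0.515), with -0.14 for Steap4 and -0.01 for Ecm1. With 1 library left out that mean ran from -0.054 (without vehicle 10) to -0.0082 (without vehicle 5), Steap4 from -0.22 (without siRNA 7) to -0.077 (without vehicle 5) and Ecm1 from -0.06 (without siRNA 4) to 0.03 (without siRNA 3). Cell cycle genes averaged -0.20 ± 0.0395 over 32 members (adjusted camera p = 0.000169, adjusted p = 0.455 with an estimated correlation), of which 1 fell, none rose and 31 did not pass, the same when adjusted over the list alone. That member was the mitotic checkpoint kinase gene Bub1 (-0.78, adjusted p = 0.0446), whose call ended without any 1 of 13 libraries, without a filter on low counts and without the 3 libraries farthest out (up to 0.0881 over the alternatives).

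The oxidative stress and NRF2 list stood higher, with 5 of 32 members past the test. Of its 32 genes, 5 rose, none fell and 27 did not pass (11 rose when adjusted over the list alone); the mean was 0.23 ± 0.0645 and the adjusted camera p 0.000321 (adjusted p = 0.455 with an estimated correlation). Beside Abcc4, Gsta2 rose from 40.5 ± 11.7 to 86.7 ± 19.8 CPM (log2 fold change 1.10 ± 0.158 SE, adjusted p = 0.000261), the quinone reductase gene Nqo1 from 15.04 ± 1.87 to 21.4 ± 3.70 CPM (0.51, adjusted p = 0.00276) and the carbonyl reductase gene Cbr3 from 6.81 ± 2.45 to 17.5 ± 11.4 CPM (1.36, adjusted p = 0.0124). Of 29 genes of endoplasmic reticulum and integrated stress, 1 rose, 1 fell and 27 did not pass (1 and 3 when adjusted over the list alone): Herpud1, of protein degradation at the reticulum (0.37), and the disulfide isomerase gene Pdia4 (-0.32). The list's mean was -0.12 ± 0.0390 (adjusted camera p = 0.00697, adjusted p = 0.455 with an estimated correlation), and its call ended without the 3 libraries farthest out and without vehicle 10 alone (mean -0.07 without vehicle 10, adjusted p up to 0.101 over the alternatives). The calls of Herpud1 and Pdia4 ended without any 1 of 5 and 12 libraries (up to 0.0550 and 0.0838), and those of Cbr3 and Pdia4 without a filter on low counts (up to 0.0659 for Cbr3). That of Pdia4 also ended with limma voom and without the 3 libraries farthest out.

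Among mitochondrial transcripts and molybdenum enzymes, mt-Rnr1, Mtarc1 and Suox changed. Of 44 nuclear-encoded oxidative phosphorylation genes, 0 passed by edgeR over all genes or over the list alone (0 unadjusted, 0 by DESeq2 or voom). Their mean was 0.05 ± 0.0106 (adjusted camera p = 0.738), which turned to -0.04 with voom and -0.06 without siRNA 4 or without the 3 libraries farthest out; Atp5b and Atp5a1, listed under their older symbols, had -0.03 and 0.02, with ranges of -0.05 to -0.01 and -0.02 to 0.04 when 1 library was left out. Of 12 mitochondrially encoded transcripts, the small ribosomal RNA mt-Rnr1 fell from 1137 ± 170 to 765 ± 111 CPM (log2 fold change -0.57 ± 0.0960 SE, adjusted p = 0.00130). The other 11 did not pass, the same when adjusted over the list alone. This list's mean (-0.03) and test were negative and its median (0.01) positive (adjusted camera p = 0.595), and the mean ran from -0.048 without siRNA 8 to -0.0011 without vehicle 10. Of 14 genes of the mARC reductase system and molybdenum enzymes, Mtarc1 fell, Suox, the sulfite oxidase gene, rose (0.29, adjusted p = 0.0439) and 12 did not pass, the same when adjusted over the list alone (adjusted camera p = 0.131). The call of Suox ended without any 1 of 16 libraries, with RLE scaling and without a filter on low counts (adjusted p up to 0.110 over the alternatives).

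Markers of hepatocytes around the central vein stood lower as a list, whereas those around the portal vein did not pass as a list. Of 14 pericentral markers, 7 fell, none rose and 7 did not pass (9 fell and 1 rose when adjusted over the list alone); the mean was -0.40 ± 0.101 (SE) and the adjusted camera p 1.96e-06 (adjusted p = 0.455 with an estimated correlation). Glul, glutamine synthetase, fell from 1494 ± 305 to 962 ± 150 CPM (log2 fold change -0.64 ± 0.12 SE, adjusted p = 0.00382) and the glutamate transporter gene Slc1a2 from 190 ± 49.7 to 99.6 ± 34.9 CPM (-0.93, adjusted p = 0.00877). Oat, ornithine aminotransferase (-0.95), and Nkd1, a target and inhibitor of Wnt signalling (-0.46), also fell. Of 15 periportal markers, 1 rose, Hal, histidine ammonia-lyase (0.42, adjusted p = 0.0367), none fell and 14 did not pass (1 rose and 2 fell when adjusted over the list alone; mean 0.05 ± 0.0624, adjusted camera p = 0.979); that mean was 0.08 without siRNA 3 and 0.02 without siRNA 4. Of 15 general hepatocyte markers, 1 fell, the fibrinogen gene Fga (-0.28, adjusted p just under 0.05), and 14 did not pass, the same when adjusted over the list alone. The hepatocyte list's mean (-0.05) and test were negative and its median (0.01) positive (adjusted camera p = 0.191); the mean was -0.13 without siRNA 4 and -0.02 without vehicle 10. The calls of Fga and Hal ended without any 1 of 15 and 12 libraries (adjusted p up to 0.130 and 0.0752 over the alternatives), that of Oat without siRNA 1, 5 or 6 (up to 0.127) and that of Slc1a2 without a filter on low counts (up to 0.0569). Those of Fga and Oat also ended without that filter, those of Fga and Hal without the 3 libraries farthest out, and that of Fga with RLE scaling.

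Sex-biased and growth-hormone-dependent liver genes stood lower as a list. The list was not split by the sex in which its genes are higher, so its direction does not speak for either sex's pattern. Of 21 such genes, 5 fell, none rose and 16 did not pass (8 fell when adjusted over the list alone); the mean was -0.56 ± 0.189 (SE) and the adjusted camera p 5.72e-06 (adjusted p = 0.417 with an estimated correlation). Cyp2d9, a male-biased steroid hydroxylase, fell from 500 ± 140 to 252 ± 97.9 CPM (log2 fold change -0.99 ± 0.188 SE, adjusted p = 0.00406). The complement gene C6 (-0.61) and the complement regulator gene Susd4 (-1.22) fell too, as did Cyp7b1. Vehicle 10 stood apart, with a mean log2 CPM of 5.70 over this list beside 4.78 to 5.27 in the other vehicle libraries. The list's median log2 fold change was -0.29, and its mean ran from -0.67 without siRNA 8 to -0.39 without vehicle 10. Slco1a1 (-3.07) is a member of this list too. The call of Susd4 ended without any 1 of 8 libraries and without a filter on low counts (adjusted p up to 0.143 over the alternatives).

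Amino acid and glucose genes changed singly. Of 38 genes of amino acid metabolism and the urea cycle, 3 rose, 3 fell and 32 did not pass, the same numbers when adjusted over the list alone (adjusted camera p = 0.564): Gpt2, an alanine aminotransferase, rose from 812 ± 87.5 to 1026 ± 53.4 CPM (log2 fold change 0.34, adjusted p = 0.00408), beside Hal, and Glul and Oat were among those that fell. Of 26 genes of glucose metabolism and insulin signalling, 2 fell, none rose and 24 did not pass (3 fell and 3 rose when adjusted over the list alone; mean -0.08 ± 0.0830, or -0.05 without vehicle 9, adjusted camera p = 0.618). Igfbp1, an insulin-repressed binding protein of insulin-like growth factors, fell from 55.6 ± 29.5 to 24.3 ± 6.80 CPM (-1.20 ± 0.226 SE, adjusted p = 0.00378), and Ppp1r3g, a glycogen-targeting phosphatase subunit, fell from 7.57 ± 4.49 to 2.71 ± 1.36 CPM (-1.50, adjusted p = 0.0112). The latter call ended without a filter on low counts (adjusted p up to 0.0563 over the alternatives).

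Bile duct markers stood higher as a list at an adjusted camera p of 0.000885 (adjusted p = 0.455 with an estimated correlation), and other cell types gave single genes. Of 13 cholangiocyte markers, 12 had a positive log2 fold change, 2 rose and 11 did not pass, the same when adjusted over the list alone. The mean was 0.42 ± 0.114. Krt23 rose from 6.90 ± 3.14 to 21.1 ± 2.77 CPM (log2 fold change 1.62 ± 0.207 SE, adjusted p = 5.12e-05) and the transcription factor gene Sox9 from 9.69 ± 1.42 to 13.3 ± 2.99 CPM (0.46, adjusted p = 0.0392). Of 15 sinusoidal endothelial markers, 1 rose, the hyaluronan receptor gene Lyve1 (0.41, adjusted p = 0.0216), and 14 did not pass, the same when adjusted over the list alone (mean -0.04, adjusted camera p = 0.127). Of 6 adipocyte markers, Cidea and the adipsin gene Cfd (-2.08, adjusted p = 0.00532) fell, the glycerol channel gene Aqp7 rose (0.98, adjusted p = 0.0290) and 3 did not pass, the same when adjusted over the list alone; the mean was -0.66 ± 0.542 and the adjusted camera p 0.0298 (adjusted p = 0.455 with an estimated correlation). The adipocyte call ended without vehicle 6, 8 or 10 or siRNA 2 or 5, with limma voom and with the hepatocyte marker sum as a covariate (adjusted p up to 0.0821 over the alternatives), and the calls of Sox9 and Aqp7 without any 1 of 12 and 6 libraries (up to 0.0804 and 0.0575). That of Sox9 also ended without the 3 libraries farthest out.

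Blood and capsule markers did not pass as lists. Of 5 erythroid markers 0 passed by edgeR over all genes or over the list alone (1 unadjusted, 0 by DESeq2 or voom; mean -0.02 ± 0.0933, adjusted camera p = 0.928), with 0.26 for Alas2 and -0.26 for Hbb-bs. Without siRNA 9 the erythroid mean was -0.35 and Hbb-bs -0.64, and without vehicle 5 they were 0.14 and -0.02. Of 5 mesothelial and capsule markers 0 passed over all genes by edgeR (1 unadjusted, 1 each by DESeq2 and voom) and 1 when adjusted over the list alone, Krt8 (-0.39, adjusted p = 0.0618; list mean -0.13 ± 0.111, or -0.20 without siRNA 4, adjusted camera p = 0.224). Platelet genes (Clec1b 0.16, Itga2b -0.10) and the acinar gene Cela1 (-0.02) came from lists with 3 and 1 members measured, too few to test. Clec1b was also a member of the sinusoidal endothelial list. Its value was 0.10 without vehicle 10. Itga2b was -0.04 without siRNA 7 and -0.17 without siRNA 4, and Cela1 -0.09 without siRNA 4 and 0.05 without siRNA 8.

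The list of immediate early genes, which are rapidly induced, stood lower with 2 of 19 members past the test, whereas clock and RNA interference genes did not pass as lists. Of 19 immediate early genes, 2 fell, none rose and 17 did not pass (3 fell when adjusted over the list alone); the mean was -0.22 ± 0.0618 and the adjusted camera p 0.000286 (adjusted p = 0.455 with an estimated correlation). The transcription factor gene Egr1 fell from 31.5 ± 8.27 to 21.2 ± 4.55 CPM (log2 fold change -0.57, adjusted p = 0.0286) and the antiproliferative gene Btg2 from 45.4 ± 11.5 to 31.4 ± 6.4 CPM (-0.53, adjusted p = 0.0413). Btg2 was also the 1 of 22 apoptosis and p53 genes that fell; none rose and 21 did not pass (1 fell and 1 rose when adjusted over the list alone), with a mean of 0.01 (-0.00073 with upper-quartile scaling), a negative median (-0.01) and a negative test (adjusted camera p = 0.979). Of 20 clock genes 0 passed by edgeR over all genes or over the list alone (2 unadjusted, 0 by DESeq2 or voom), with a mean of -0.03 and a positive median (0.06) and test (adjusted camera p = 0.941), and values of 0.09 for Tef (0.04 without vehicle 7) and 0.03 for Dbp (-0.02 without siRNA 4). Of 15 genes of siRNA uptake and RNA interference, 1 rose, Drosha, the microRNA-processing nuclease (0.18, adjusted p = 0.0466), and 14 did not pass, the same when adjusted over the list alone (adjusted camera p = 0.115). The calls of Btg2 and Drosha ended without any 1 of 13 and 16 libraries (adjusted p up to 0.0836 and 0.273 over the alternatives) and that of Egr1 without vehicle 5 or 7 or siRNA 6 or 8 (up to 0.0787). All 3 also ended without a filter on low counts and without the 3 libraries farthest out, and that of Drosha with upper-quartile scaling.

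**Figure D3:**
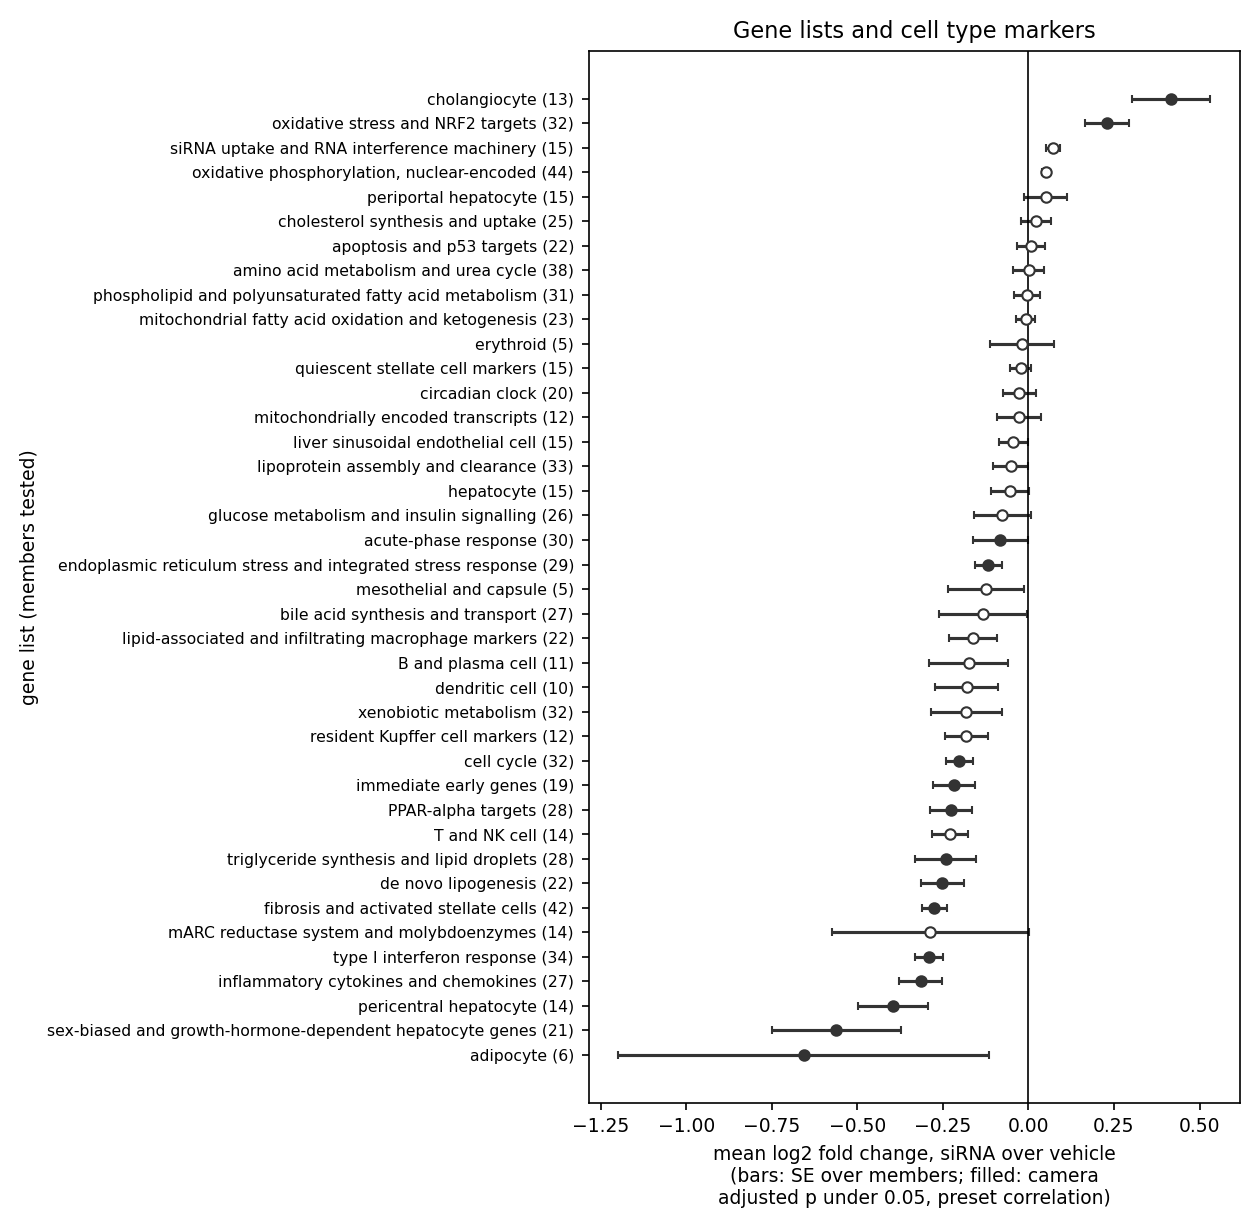
Mean log2 fold change of siRNA over vehicle for 40 gene lists and cell type marker sets (points, with SE over members as bars; number of members tested in parentheses). Filled points mark the 15 lists past the camera test with the preset correlation, 13 lower and 2 higher (oxidative stress and cholangiocyte).

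Across the 40 lists, 15 passed the camera test with the preset correlation, 13 lower and 2 higher. With an estimated correlation 0 passed (lowest adjusted p 0.417, 3 lists at an unadjusted p under 0.05), and 6 passed fry: interferon (0.0232), sex-biased genes (0.0232), triglyceride and lipid droplets (0.0457), pericentral markers (0.0468), adipocyte markers (0.0457) and the mARC list (0.0170). The first 5 of these passed camera as well. The mARC list holds the siRNA's own target: its other 13 members had a mean of -0.00167 ± 0.0383 (SE) and a fry adjusted p of 0.974 without Mtarc1, and 2 lists then passed fry. Beside T and NK cells, some other lists not past camera passed it with 1 library left out: macrophage markers without vehicle 9 or 10 or siRNA 1 or 7, lipoprotein genes without vehicle 2 or siRNA 4 (-0.11 without siRNA 4) and xenobiotic genes without vehicle 2 or siRNA 8 (-0.23 without siRNA 8). The mARC, hepatocyte and sinusoidal endothelial lists did so without vehicle 2. Among 100 splits of the same libraries, 22 gave 15 or more lists past the preset-correlation test, the real split included, so the number of lists past was not larger than other groupings of these animals gave. The number of changed genes was larger than in any of the others, which gave at most 8 against 480. The interferon list had as small a p in 4 of 100 splits, but some list of the 40 had one as small as its 1.88e-12 in 30; the sex-biased and adipocyte lists had as small a p as their own in 5 each, triglyceride genes in 7 and pericentral markers in 8, and the other 10 lists past the test in 10 to 23.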

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

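The comparison of the interferon list with other immune lists, the count of splits by the smallest p of any list, that of pericentral with periportal markers, the repeats of the macrophage and periportal tests with 1 library left out and the fit without vehicle 10 and siRNA 4 and 8 are tests chosen only after the result was seen.

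Beside Mtarc1, 247 genes fell, and none of the 99 other groupings run, each keeping 2 to 7 of the 9 siRNA libraries together in the group of 9, came near: 1 of 100 splits, the real one, gave as many lower genes (248, highest other 4), 1 of 100 as many higher genes (232, highest other 4) and 1 of 100 as many changed genes (480, highest other 8). Reduction of unintended transcripts by the siRNA's seed, a short match that small RNAs find in 3' UTRs, may account for a part: the heptamer ATATGGA occurred in the 3' UTRs of 43 of 230 fallen genes (18.7%) and in 8.77% of 12880 genes (Bonferroni p = 0.0233), 0 of 1000 length-matched gene sets had as small a p for any heptamer, and it lies in the coding part of Mtarc1 transcripts. It was in 12 of 222 risen genes (5.4%, p = 0.978) and in 2 of the 11 lower genes named, Mapk3 and Slc16a2, so most of the fallen genes with a searched 3' UTR do not carry it, and 17 fallen genes had no 3' UTR to search. In the risen genes CTTTCTT, which is not in Mtarc1 transcripts, had a Bonferroni p of 0.029, with as small a p in 362 of 1000 length-matched sets, so such a Bonferroni p also arose where no seed would act. The place of ATATGGA in Mtarc1 adds little by itself, because any heptamer can lie by chance in transcripts of 1239 to 2152 nt. The siRNA's sequence is not given in the sources used here, base composition was not matched, and with vehicle as the control the loss of Mtarc1, effects of siRNA delivery and other matches stay open as untested explanations of the rest.

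The interferon list stood lower in siRNA livers, with a mean log2 fold change of -0.291. Fewer macrophages and monocytes may account for a part: with their marker mean as a covariate the list's mean was -0.279, or 95.8% of its size, but vehicle 10, lowest in those markers and highest in the interferon mean, weighs on this, and without it the mean was -0.171 ± 0.0367 (SE), or 63% of its size, and the bound of 50% was not passed by 2 SE. Chance stays open: the list alone reached as small a camera p in 4 of 100 splits (smallest other 1.4e-22 beside the real 1.88e-12), but it was singled out as the smallest of 40, some list reached that p in 30 of 100 splits, and its adjusted p = 0.417 with an estimated correlation. A general fall of immune transcripts cannot be told apart, because the median of the means of 4 immune cell lists was -0.181, between 0 and the interferon value, none of those lists passed, and 3 of the means moved far with 1 library (Kupffer -0.031 and B and plasma cells -0.043 without vehicle 3, T and NK cells -0.072 without vehicle 7), while that of dendritic cells stayed between -0.225 and -0.138. An effect of Mtarc1 loss or of the siRNA itself on interferon signalling may contribute and was not tested apart.

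Pericentral hepatocyte markers stood lower, with a mean log2 fold change of -0.396. A shift of the sampled tissue toward periportal regions would need a rise of periportal markers, whose mean was 0.05 ± 0.0624 (SE over members). This mean lay below the bound of 50% of the pericentral change by more than 2 SE, which leave out variation between animals. It did not do so without vehicle 10 or siRNA 3, 5, 6 or 7 (0.0837 ± 0.0639 without siRNA 3), so such a shift stays open. The 3 libraries farthest out together do not carry the difference, since without vehicle 10 and siRNA 4 and 8 the mean was -0.418, or 106% of its size. They pull in opposite directions, with -0.319 without vehicle 10 alone and -0.45 without siRNA 8 alone. This fit therefore cannot speak for other sets of libraries. The mean was -0.349, -0.327 and -0.33 without siRNA 1, 5 or 6 alone, and these were not left out together. Chance stays open for the list as a whole: 8 of 100 splits gave as small a camera p, the smallest other being 8.54e-10 beside the real 1.47e-07. It could therefore be ordinary variation among animals in a set of genes that vary together, a shift of the sampled region or an effect of the treatment.

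The number of lists past the test is not set apart from chance, as 22 of 100 splits gave 15 or more, with 3 to 22 lists and a mean of 11.9 in the other 99.

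Of 302 sets of values per group, 25 held a library far from the rest, where chance gives about 1 in 20, or 15.1. Vehicle 10 held 12 of the 25. In it Pls1 was at 1.57 CPM and Aqp7 at 0.262 CPM, the lowest of the vehicle group. Uso1 (172 CPM), Ttc7b (32.8), Pcnp (49.9), Cyp7b1 (154), C6 (419), Susd4 (15.4) and Alas2 (113) were the highest there. In the same library the mean log2 CPM was lowest for quiescent stellate (4.47) and macrophage markers (3.76) and highest for sex-biased genes (5.70). Vehicle 7 had the highest Nqo1 (19.8 CPM) and the lowest Tef (153 CPM) and mesothelial marker mean (3.40 log2 CPM). Vehicle 1 had the highest Igfbp1 (135 CPM) and the lowest adipocyte marker mean (3.34 log2 CPM). Itga2b was lowest in vehicle 2 (2.14 CPM) and Mmp13 in vehicle 3 (0.884 CPM). Among siRNA libraries, Fam234b was highest in siRNA 8 (51.7 CPM) and Orm2 in siRNA 4 (84.1 CPM). In siRNA 9 Hbb-bs (163 CPM) and the erythroid mean (5.59 log2 CPM) were highest. The macrophage mean was lowest in siRNA 8 (4.02 log2 CPM) and the periportal mean in siRNA 3 (8.13 log2 CPM).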

How the results depend on the processing

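The fit without vehicle 10 and siRNA 4 and 8 and the fry test without the siRNA target were chosen only after seeing the data. Mtarc1 kept its direction and call in every alternative (-4.05 to -3.96 with 1 library left out). Of 87 other named genes that passed, 52 passed in every alternative and 62 without any 1 library; of 15 lists, 12 passed in every alternative setting of the same test. None of the results past its threshold changed sign. With 1 library left out, 348 (without siRNA 5) to 540 genes (without vehicle 10) changed, 157 to 238 higher and 175 to 302 lower, with 14 to 20 lists past; without the 3 libraries together 443 changed, 337 of them shared. Scaling by RLE or upper quartiles gave 455 and 486 genes, voom 680, a mean of 1 CPM 478 and the file number as a covariate 586. At these depths the simulated test recovered 42% of 1.3-fold changes, which limits what can be said of small changes.

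The counts of genes changed, genes higher and genes lower moved by more than 1.5 times as follows; the cause was not tested except where given. DESeq2 called 766 genes (362 higher, 404 lower), the surrogate variable 1491 (831 and 660) and the hepatocyte marker sum 1002 (476 and 526). Without a filter, with 30146 genes tested, 289 passed (136 and 153). An adjusted p under 0.1, a looser threshold, gave 853, and a minimum fold of 1.2, a stricter one, 68. Of lists, 0 passed with an estimated correlation, 3 of them at an unadjusted p under 0.05, and 6 with fry, or 2 with the target left out of the mARC list. Some means of lists not past the test moved with 1 library: without siRNA 4 the hepatocyte mean was -0.13 and the lipoprotein mean -0.11, and without vehicle 10 the cholesterol mean was 0.07. Those of mitochondrial fatty acid oxidation, apoptosis, cholesterol, amino acid, phospholipid and clock genes, all near 0, changed sign with 1 library left out.

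Values near 0 that changed sign, none of them past a test, were these; the cause was not tested. The amino acid mean was -0.0097 with DESeq2, -0.0033 with RLE, -0.0081 with upper quartiles, -0.0048 with the surrogate variable, -0.036 with voom, -0.0050 at 1 CPM, -0.0074 without a filter and -0.038 without the 3 libraries. The phospholipid mean was 0.00015 with the file number, 0.0076 with the hepatocyte sum and 0.0070 without the 3 libraries. With the hepatocyte sum, apoptosis was -0.020, hepatocyte 0.0017, fatty acid oxidation 0.027, erythroid 0.065, Mtarc2 0.051, Ecm1 0.031 and Slc40a1 -0.027; apoptosis was -0.00073 with upper quartiles. With voom, Cd5l was -0.016, Cd8a 0.021, Dbp -0.022, Atp5a1 -0.0080 and oxidative phosphorylation -0.043; the last 3 were -0.025, -0.020 and -0.061 without the 3 libraries.

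With 1 library left out, ranges that crossed 0 were -0.024 to 0.040 for Atp5a1, -0.033 to 0.12 for Cd5l, -0.25 to 0.16 for Cd8a, -0.090 to 0.050 for Cela1, -0.024 to 0.067 for Dbp, -0.064 to 0.033 for Ecm1, -0.085 to 0.035 for Mtarc2 and -0.059 to 0.083 for Slc40a1. List means ran from -0.056 to 0.035 for amino acid, -0.013 to 0.021 for apoptosis, -0.029 to 0.074 for cholesterol, -0.044 to 0.000060 for clock, -0.35 to 0.14 for erythroid, -0.044 to 0.016 for fatty acid oxidation, -0.061 to 0.098 for oxidative phosphorylation and -0.018 to 0.0093 for phospholipid genes.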

Other observations

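The Fisher exact tests in this part, their gene lists and the genes singled out were chosen only after the result was seen. These tests count genes as independent, although genes of a list can vary together between animals. They were not run on the splits of the libraries, so their p-values do not measure variation between animals. Nor were the genes compared matched on expression level. Genes first named in this part, and Slco1a1, were not tested in the alternatives. Lysosomal genes were found among the genes that fell: 8 of 67 measured genes of lysosomal proteins fell (11.9%), beside 1.74% of the 14234 genes tested other than Mtarc1 (one-sided Fisher exact p = 1.98e-05; 0.000865 without the 2 strongest). After Arsb and Cln5 these were Gba, glucocerebrosidase (log2 fold change -0.47 ± 0.0698 SE, adjusted p = 0.000355), Npc1, which moves cholesterol out of lysosomes (-0.45, adjusted p = 0.00631), Hgsnat (-0.28), the sialic acid exporter gene Slc17a5 (-0.25), the sulfatase gene Arsa (-0.24) and the channel gene Mcoln1 (-0.20). Complement genes also fell more often than other genes, 7 of 39 (17.9%, one-sided Fisher exact p = 4.17e-06; 0.000403 without the 2 strongest). C8a, of the membrane attack complex, fell from 495 ± 106 to 312 ± 71.8 CPM (-0.67 ± 0.136 SE, adjusted p = 0.00711) and C3, the central component, from 7260 ± 702 to 6070 ± 508 CPM (-0.26, adjusted p = 0.0452). The others were C6, Cfd, C4a (-0.81), C4bp (-0.20) and the inhibitor gene Serping1 (-0.27). Of these, C6 was also on the sex-biased list and Cfd on the adipocyte list. None of the other members of either list rose past the test in edgeR. The gene lists were written after the fallen genes had been seen, so both are hypotheses.

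Solute carrier genes changed in both directions: 10 of 252 rose (3.97%, beside 1.63% of all), with a one-sided Fisher exact p of 0.00844 that went to 0.0505 without the 2 strongest, and 12 fell (4.76%, beside 1.74% of all, one-sided Fisher exact p = 0.00153), Slc16a2 and Slc1a2 among them. Slc1a1, a glutamate transporter, rose from 0.301 ± 0.182 to 1.57 ± 0.852 CPM (log2 fold change 2.38 ± 0.378 SE, adjusted p = 0.000717), and Slc28a1, a nucleoside transporter, from 0.396 ± 0.168 to 1.12 ± 0.359 CPM (1.49, adjusted p = 0.00157). The organic ion transporter genes Slc22a4 (0.79), Slc22a29 (1.14) and Slc22a27 (0.61) and the zinc transporter gene Slc39a4 (0.51) rose too.

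Single animals held transcripts at levels far from all others. H19, an imprinted noncoding RNA of fetal liver, was at 211 CPM (3523 reads) in siRNA 1 and at 0.944 to 11.9 CPM in the other 18 libraries. Slco1a1, a bile salt and steroid transporter, was at 253 CPM in vehicle 10 and at most 17.7 CPM elsewhere, and the urinary protein gene Mup7 at 803 CPM in vehicle 10 and at most 38.9 CPM elsewhere. Most siRNA libraries were also low beside the other vehicle libraries, where Slco1a1 was at 3.74 to 15.2 CPM and Mup7 at 2.83 to 37.4 CPM. Slco1a1 was at 0.659 to 2.15 CPM in siRNA libraries other than siRNA 4 (8.82) and siRNA 8 (17.7). Mup7 was at 0.359 to 2.59 CPM in those other than siRNA 4 (12.2), siRNA 8 (38.9) and siRNA 9 (6.2). Neither gene was tested without vehicle 10. Neither Slco1a1 (log2 fold change -3.07, adjusted p = 0.0731) nor Mup7 (-3.57, adjusted p = 0.117) nor H19 (2.69, adjusted p = 0.114) passed between the groups. Beside mt-Rnr1, the large mitochondrial ribosomal RNA mt-Rnr2 had a log2 fold change of -0.20 and did not pass (adjusted p = 0.205).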
